A study of Mus musculus with 6 samples.

How the data were processed

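Skin from streptozotocin-diabetic C57BL/6 mice was collected on day 7 after wounding, per the labels, from 3 samples given PBS and 3 given rFGF4. Total RNA was poly(A)-selected, fragmented and made into strand-marked (dUTP) libraries, which were sequenced as paired ends, per the labels' protocols. Poly(A) selection favours intact polyadenylated transcripts, so RNA integrity and the removal of short inserts can change the yield of short against long transcripts. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR and the build GRCh38, with versions, roles and order not given in the sources used here. GRCh38 is a human build, whereas the organism and the gene symbols are those of mouse; which reference was used is therefore open. Whether counting used the strand mark is not stated, so antisense and overlapping genes are uncertain, as are near-identical copies.

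A single table of the whole series was used. Its 6 value columns are read as FPKM made by the authors: the file header names no unit, and FPKM is taken from the values, which are not whole and sum to 304717 to 319807 per library, and from StringTie in the submitters' processing notes. The deposited table also holds a p-value and a q-value per gene; the q-value equals the Benjamini-Hochberg adjustment of the p-value. The deposited fold column is the ratio of the group means of FPKM in 99.9% of its lines, and the deposited log2 column is the log2 of that ratio. Only genes whose value passed 1 in at least 1 library are listed (smallest maximum 1.0001), so genes below that level were not analysed here. Columns were matched to samples by name, and 0 columns of values lacked a sample. Depth is unknown because FPKM keep no counts. Whole reads could not be recovered: for 3902 genes scanned, at most 12.8% to 14.3% of values per library lay within 0.05 of a whole multiple, where chance gives 10%. The precision of single values is therefore known only from the spread between 3 libraries.

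The design fixed before the data were examined foresaw counts or FPKM, and its FPKM branch was used. Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 0.1) with limma-trend (robust empirical Bayes, two-sided), with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. With 3 against 3 libraries an exact permutation test of a single value cannot go below p = 0.1, so none was used. In all, 37 gene lists were fixed before the data were examined, and the 36 with at least 5 tested members were tested with camera at its preset correlation of 0.01; calls with an estimated correlation, with fry and on ranks are alternatives. Counts adjusted over the list alone use the limma p-values of the list's members. The genes named are Fgf4, Itgb1 and Fgfr1 to Fgfr4; the 8 largest rises and 8 largest falls among called genes with a proper symbol, a mean of at least 1 FPKM and groups that do not overlap; and up to 4 members per list with the smallest unadjusted p. A gene may fall under more than 1 part of that rule, and 1 gene that the rule names is not reported here. Ribosomal protein genes as a class, 14 further genes and the pathways of the table's own annotation were chosen after the data were seen.

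Transcript lengths, GC content and positions came from GENCODE M21 on GRCm38, where 15482 symbols (96%) matched; the length of a gene is that of its longest APPRIS-principal transcript, or of its longest transcript where none is so marked. The build of the authors' values may differ, so positions are from this annotation alone. Lengths were known for 14193 of the tested genes (96.7%). To remove the length trend, deviations from the gene's mean were fitted on log2 length in each library by loess (span 0.3, degree 1, symmetric) and the fit was subtracted; genes with no length were left out. Further alternatives were other pseudocounts (1 and 0.01), no filter or at least 5 FPKM, a 2-fold threshold, the replicate number as a block, a skeletal muscle score as a covariate and each library left out in turn. Chosen after the data were seen were removal of the length trend by principal or longest transcript, leaving out transcripts under 1000 bases, median centring, scaling each library to 1 common total and quantile normalization. Scripts were tested on simulated data: in 3 runs on 14676 genes with 200 changed, limma recovered 41.7% of genes changed by 1 and 81.0% of those changed by 2 on the log2 scale with 6 false calls on average. With a length trend put into the simulated data there were 1880 false calls on average, and 5.67 after its removal. That trend was built from the same annotated lengths that the correction uses, with independent noise per gene. The run therefore checks the script and does not show how fully the trend of the real libraries is removed. R 4.3.3, limma 3.58.1, statmod 1.5.0 and Python 3.11.15 were used. No batch is given in the labels, so none was tested.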

Results

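RNA was measured in skin taken 7 days after wounding from C57BL/6 mice made diabetic with streptozotocin, a toxin of insulin-producing cells. The skin had received either phosphate-buffered saline (PBS, 10 µl per day) or recombinant fibroblast growth factor 4 (rFGF4, 100 ng/ml, 10 µl per day), with 3 poly(A) libraries in each group. The deposited FPKM table lists 16131 genes, of which 14676 reached 1 FPKM in at least 3 libraries and were tested. The listed values summed to 313638, 319807 and 310256 FPKM in PBS replicates 1 to 3 and to 311668, 304717 and 311311 FPKM in rFGF4 replicates 1 to 3. FPKM keep no read counts, so the sequencing depth behind each value is unknown. Pearson's r of log2 FPKM across genes, which are not independent replicates, was 0.944 to 0.958 within groups and 0.901 to 0.944 between groups. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Fold changes below are on the log2(FPKM + 0.1) scale and understate the change of low genes.

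The comparison asks which transcripts differ between rFGF4-treated and PBS-treated diabetic skin. Of 26 genes of the collagen-rich matrix that fibroblasts lay down, 18 rose with rFGF4, among them Lox, the enzyme that cross-links collagen, at 122 ± 1.88 FPKM against 53.2 ± 7.60 (SD, n = 3 each). Fold changes also rose with transcript length, and with that trend removed Lox was the 1 member called (set test adjusted p = 0.714 with an estimated correlation as deposited, and 0.932 with the trend removed). Receptors for TGF-beta rose as well, with Tgfbr2 at 40.7 ± 1.39 FPKM against 20.98 ± 0.789. Mrc1, the mannose receptor of alternatively activated macrophages, rose from 11.5 ± 0.675 to 34.7 ± 0.358 FPKM. Ndufa1, a subunit of complex I of the mitochondrial respiratory chain, fell from 65.1 ± 1.61 to 11.9 ± 2.79 FPKM. The ribosomal protein gene Rps29 fell from 272 ± 20.6 to 28.6 ± 9.71 FPKM. In each of these genes all 3 rFGF4 libraries lay beyond all 3 PBS libraries. Ndufa1 and Rps29 have short transcripts of 419 and 390 bases, in length classes where 31.2% and 29.1% of genes were called lower. Both were also called with the length trend removed (limma adjusted p = 0.00535 and 0.00169), but falls of this size were not particular to them.

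By limma with Benjamini-Hochberg adjustment, 1773 of the 14676 genes changed, 1241 higher and 532 lower with rFGF4, so that 70% of calls were higher. Of the 1773, 516 changed at least 2-fold, 104 of them higher and 412 lower. The groups did not overlap in 5608 genes (38.2%), where chance gives 10%. The median log2 fold change of all tested genes was 0.194, and 0.014 after each library was centred on its median. Centring left 755 calls, 18.3% of them higher, and quantile normalization left 749, 31.4% higher. Fold changes rose with transcript length (Spearman's rho 0.502 across 14193 genes, which are not independent replicates). Removing the length trend from each library, an alternative chosen after the data were seen, left 306 calls, 77 higher and 229 lower. In that setting 4 higher and 69 lower genes were called without PBS replicate 1, 8 and 67 without PBS replicate 2, 23 and 96 without PBS replicate 3, and 30 and 162, 43 and 179 or 39 and 138 without rFGF4 replicate 1, 2 or 3. Of the 306, 43 higher and 220 lower genes were also called as deposited. The number of calls depended on single libraries, at 156, 203 and 225 without PBS replicate 1, 2 or 3 and at 397, 890 and 337 without rFGF4 replicate 1, 2 or 3. Of 60 called genes chosen by the naming rule, 16, 16 and 21 were called without PBS replicate 1, 2 or 3 and 22, 39 and 23 without rFGF4 replicate 1, 2 or 3. The 13 called in all 6 of those fits were Cox6c, Lox, Mrc1, mt-Nd3, Ndufa1, Ndufa4, Rab26os, Rpl31-ps9, Rps29, Spred1, Stfa3, Tgfbr2 and Uqcrb.

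**Figure D1:**
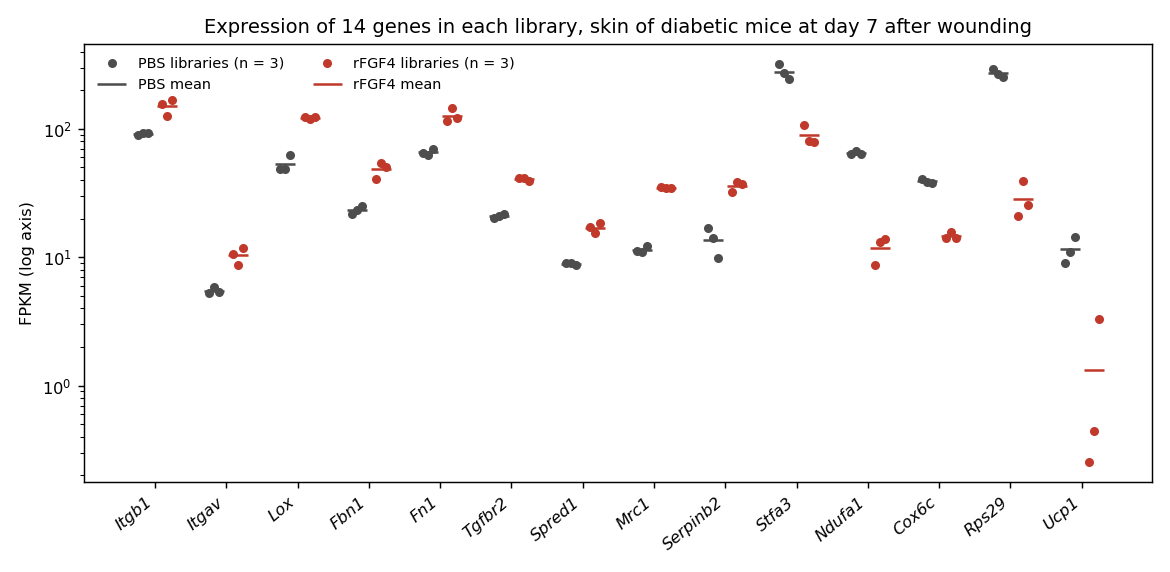
FPKM on a log axis for 14 genes in the 3 PBS (grey) and 3 rFGF4 (red) libraries; points are libraries and bars are group means. Mrc1 lies near 11.5 FPKM in PBS and 34.7 in rFGF4 libraries with little spread, whereas Ucp1 varies widely between the rFGF4 libraries (mean 1.33, SD 1.70).

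Among genes of FGF signalling and cell adhesion, Itgb1, which encodes the integrin beta 1 chain of receptors for collagen and fibronectin, rose 1.64-fold. It measured 91.3 ± 1.69 FPKM in PBS and 151 ± 21.7 in rFGF4 libraries (log2 fold change 0.71, SE 0.149, limma adjusted p = 0.0322). Itgb1 is a protein-coding gene on chromosome 8, from 128685654 to 128733200 on the plus strand of GRCm38 (GENCODE M21). The study's title, written with these libraries in hand, names integrin beta 1, so this rise is not independent evidence of its direction. Leaving out rFGF4 replicate 2 kept the Itgb1 call (limma adjusted p = 0.0295), whereas it was lost without PBS replicate 1 (0.101), 2 (0.107) or 3 (0.0822) and without rFGF4 replicate 1 (0.0793) or 3 (0.085). Its log2 fold change was 0.53 (adjusted p = 0.121) with median-centred libraries, 0.86 (adjusted p = 0.0345) with quantile normalization, 0.78 (adjusted p = 0.0676) with a skeletal muscle score as covariate and 0.40 (adjusted p = 0.269) with the length trend removed. Fgf4 itself has no entry in the table, and Fgfr4 stayed below the filter. The receptor Fgfr1 measured 24.3 ± 3.14 and 34.6 ± 2.94 FPKM and did not pass (adjusted p = 0.0569), nor did Fgfr2 (log2 fold change 0.19, adjusted p = 0.768) or Fgfr3 (-0.30, adjusted p = 0.418).

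Of 24 integrin subunits, 4 rose over all genes and 4 adjusted over the list alone, with the median log2 fold change at 0.36 (camera adjusted p = 0.155, and 0.936 with an estimated correlation). They were Itgb1, Itgav, which pairs into receptors for vitronectin and latent TGF-beta (5.48 ± 0.318 to 10.4 ± 1.55 FPKM), the collagen receptor chain Itga11 (limma adjusted p = 0.0445) and Itga9 (limma adjusted p = 0.0452). Without rFGF4 replicate 2 the list had 2 calls, without PBS replicate 2 it had 1, and without PBS replicate 1, PBS replicate 3 or either other rFGF4 library it had 0. The integrin median was 0.014 with the length trend removed, where limma called 0 members over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.715). The list passed camera without PBS replicate 3 (adjusted p = 0.0432) or rFGF4 replicate 2 (0.04). The focal adhesion and actin motility genes, which link integrins to the moving cytoskeleton, had 6 of 32 members higher and 14 adjusted over the list alone. Rock1 and Rock2, kinases that drive actomyosin contraction, rose by 0.74 and 0.75 on the log2 scale, and the adaptors Vcl and Fermt2 by 0.67 and 0.77. The list's median of 0.35 passed camera at adjusted p = 0.0456, but not with an estimated correlation (adjusted p = 0.714 with an estimated correlation), with median-centred libraries (0.0889), without PBS replicate 1 (0.131) or without rFGF4 replicate 3 (0.203). Without rFGF4 replicate 2, 3 of its members were called, and 0 without any other single library. Its median was 0.044 with the length trend removed (camera adjusted p = 0.257), where limma called 0 members over all genes.

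FGF-MAPK feedback targets, the inhibitors and transcription factors that FGF receptor signalling induces, were higher in 2 of 17 members and in 4 adjusted over the list alone (median log2 fold change 0.38, camera adjusted p = 0.0568, and 0.714 with an estimated correlation). Spred1, an inhibitor of Ras signalling, rose from 8.86 ± 0.206 to 17.0 ± 1.44 FPKM, and the phosphatase Dusp4 from 1.91 ± 0.168 to 3.18 ± 0.283 FPKM (limma adjusted p = 0.00785 and 0.036). Myc (limma adjusted p = 0.0614) and Spry4 (0.0637) had positive log2 fold changes of 0.52 and 0.75 that did not pass. The list passed camera with the length trend removed (median 0.21, adjusted p = 0.0475, and adjusted p = 0.932 with an estimated correlation), with median-centred libraries (0.0288), and without PBS replicate 2 (0.0388), PBS replicate 3 (0.0461) or rFGF4 replicate 1 (0.0388). Dusp4 was called in none of the 6 fits that left out 1 library (limma adjusted p 0.0619 to 0.121). With the length trend removed limma called 0 members of the list over all genes and 1 adjusted over the list alone. Of 9 FGF ligands and receptors, 2 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.449, and 0.936 with an estimated correlation). These were Fgf2, a fibroblast mitogen, at 1.85 ± 0.217 and 3.46 ± 0.330 FPKM, and Fgf7, the keratinocyte growth factor, at 3.96 ± 1.36 and 10.1 ± 3.28 FPKM. Only Fgf2, without rFGF4 replicate 2, stayed called when a library was left out. Neither Fgf2 nor Fgf7 was called with the length trend removed.

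All 26 fibroblast matrix genes had positive fold changes, 18 rose over all genes tested and 26 adjusted over the list alone (median log2 fold change 0.83, or 0.64 above the median of all genes, camera adjusted p = 9.84e-10). The set test was not passed with an estimated correlation (adjusted p = 0.714 with an estimated correlation). Beside Lox (log2 fold change 1.21, limma adjusted p = 0.00728), Fbn1, the fibrillin of elastic microfibrils, rose from 23.3 ± 1.63 to 48.4 ± 6.82 FPKM and Fn1, fibronectin, from 65.5 ± 3.72 to 127 ± 15.2 FPKM. Pdgfra, the receptor that marks fibroblasts, rose 2.14-fold (limma adjusted p = 0.0186). Over all genes, 1, 3 and 3 members were called without PBS replicate 1, 2 or 3, and 6, 11 and 3 without rFGF4 replicate 1, 2 or 3, while 20 to 26 passed adjusted over the list alone. In those fits the list's camera adjusted p lay between 8.22e-11 and 6.34e-08. These are long transcripts, with a median of 5332 bases. All 26 lay above the median of their length class, and with the length trend removed the list's median was 0.44 (camera adjusted p = 2.86e-10, and adjusted p = 0.932 with an estimated correlation), with 1 member called over all genes, Lox (limma adjusted p = 0.0264), and 9 adjusted over the list alone.

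Matrix proteases and their inhibitors, which remodel that matrix, were higher in 6 of 21 members and in 11 adjusted over the list alone (median 0.80, camera adjusted p = 0.00593, and adjusted p = 0.936 with an estimated correlation). The metalloproteinases Adamts1, Adamts5 and Adam12 rose by 0.65, 0.84 and 0.95 on the log2 scale and the inhibitor Timp2 by 0.87. The call was lost without PBS replicate 1 (camera adjusted p = 0.0627), and 0, 1 and 0 members were called without PBS replicate 1, 2 or 3 and 2, 5 and 0 without rFGF4 replicate 1, 2 or 3. Length-corrected values had a median of 0.48 (camera adjusted p = 0.000606, and adjusted p = 0.932 with an estimated correlation), with 0 members called by limma, also adjusted over the list alone, and 7 at an unadjusted p under 0.05. In the TGF-beta pathway 5 of 18 genes rose and 7 adjusted over the list alone, with all 18 fold changes positive (median 0.60, camera adjusted p = 0.00295, and adjusted p = 0.714 with an estimated correlation). The receptors Tgfbr2, Tgfbr3 and Tgfbr1 rose 1.93-fold, 1.89-fold and 1.56-fold, and the ligand gene Tgfb3 1.47-fold. Tgfbr2 was called with each library left out in turn; the pathway kept 1 call without each PBS replicate and 2, 3 and 1 without rFGF4 replicate 1, 2 or 3. Its median was 0.23 with the length trend removed (camera adjusted p = 0.0475, and adjusted p = 0.932 with an estimated correlation). Tgfbr2 was the 1 member called by limma in that setting. Among 11 regulators of mesenchymal transition, Prrx1 (12.3 ± 1.42 to 24.4 ± 3.29 FPKM) and Twist2 rose and S100a4 fell (231 ± 43.3 to 78.9 ± 39.0 FPKM), or 5 higher and 1 lower adjusted over the list alone. That list did not pass (median 0.56, camera adjusted p = 0.325, and 0.936 with an estimated correlation). Prrx1 stayed called only without PBS replicate 3 or rFGF4 replicate 2, and Twist2 and S100a4 only without rFGF4 replicate 2. Limma called 0 members of this list with the length trend removed.

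Among called genes with a proper symbol, a mean of at least 1 FPKM and groups that do not overlap, the largest rises were those of Il1rl1, the receptor for interleukin 33 (4.64 ± 0.897 to 21.5 ± 15.1 FPKM), and Ccn3, a matricellular protein gene (3.48 ± 1.14 to 14.4 ± 5.96 FPKM). Serpina3b (log2 fold change 1.72), Mrc1 (1.59), Thbs4, Lrrn4cl (1.44), Serpinb2 (1.43) and Gfpt2 (1.41) followed, with limma adjusted p between 0.00154 and 0.0411. After removal of the length trend Mrc1, Lrrn4cl, Serpinb2 and Gfpt2 passed, while Il1rl1 (limma adjusted p = 0.164), Ccn3 (0.0888), Serpina3b (0.061) and Thbs4 (0.14) did not. Il1rl1 and Ccn3 passed only without rFGF4 replicate 3 when libraries were left out, Serpina3b and Thbs4 only without PBS replicate 1, with the limma adjusted p of these 4 otherwise between 0.0528 and 0.11. Lrrn4cl was lost without PBS replicate 1, PBS replicate 2 or rFGF4 replicate 3 (up to 0.0833), Serpinb2 without PBS replicate 2 or rFGF4 replicate 3 (up to 0.0614) and Gfpt2 without PBS replicate 1 or 3 (up to 0.0607). Of the 8 largest falls chosen in the same way, only that of Ucp1 was on a transcript above 500 bases. Ucp1, the uncoupling protein of brown fat, with a principal transcript of 1636 bases, fell from 11.5 ± 2.75 to 1.33 ± 1.70 FPKM (limma adjusted p = 0.0342), and stayed called only without rFGF4 replicate 3, with a log2 fold change of -4.71 there and -3.07 without rFGF4 replicate 1 (limma adjusted p otherwise up to 0.104). The others had transcripts of 300 to 477 bases: the small RNA genes Rn7s2 (9.79 ± 11.3 to 0.354 ± 0.287 FPKM) and Rn7s1 (9.81 ± 11.3 to 0.395 ± 0.298 FPKM) fell by 4.02 and 3.91, Rpl31-ps9 by 3.46, Rab26os by 3.42, Rps29 by 3.29 and the metallothionein Mt4 by 3.12 on the log2 scale, and Rn7sk fell from 9.97 ± 3.97 to 0.885 ± 0.694 FPKM. Mt4 stayed called only without rFGF4 replicate 2, at -3.75 (limma adjusted p otherwise up to 0.0865), and Rn7sk was lost without PBS replicate 1, PBS replicate 2 or rFGF4 replicate 1 (up to 0.0766). PBS replicate 1 had 22.9 and 22.8 FPKM of Rn7s2 and Rn7s1, and without it their log2 fold changes were -3.09 and -2.99 (limma adjusted p = 0.0788 and 0.0833). Rn7s1 and Rn7s2 are near-identical copies that were called in no fit with a library left out, Rpl31-ps9 is a pseudogene that shares reads with its parent, and Rab26os is antisense with no stated use of strand in counting, so their values are uncertain. Rn7s1, Rn7s2 and Rn7sk are annotated as miscellaneous RNA and not as protein-coding genes. How much of such RNA passed the poly(A) selection of each library is unknown, so their falls cannot be read as changes of expression.

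Transcripts of 400 to 600 bases had a median log2 fold change of -0.58, with 138 of 443 genes lower and 8 higher. Above 6000 bases the median was 0.43, with 340 of 1456 genes higher. Within each library, log2 deviations from the gene mean correlated across genes with length at rho -0.355, -0.339 and -0.366 in PBS replicates 1 to 3 and at 0.418, 0.206 and 0.322 in rFGF4 replicates 1 to 3. Ribosomal protein genes, a class read after the data were seen, were lower in 47 of 86 members and higher in 0 by limma, with 63 and 0 at an unadjusted p under 0.05 and a median of -1.07. Their share of the listed FPKM was 8.41%, 7.25% and 7.31% in the PBS and 3.69%, 5.24% and 4.28% in the rFGF4 libraries. The median was -2.21 for the 12 of at most 500 bases, -1.37 for 13 of 500 to 700, -0.64 for 31 of 700 to 1000 and -0.56 for 30 above 1000 bases. Without PBS replicate 1, 2 or 3 the count of lower ribosomal protein genes was 21, 25 or 27, and without rFGF4 replicate 1, 2 or 3 it was 37, 51 or 26. After removal of the length trend it was 35.

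**Figure D2:**
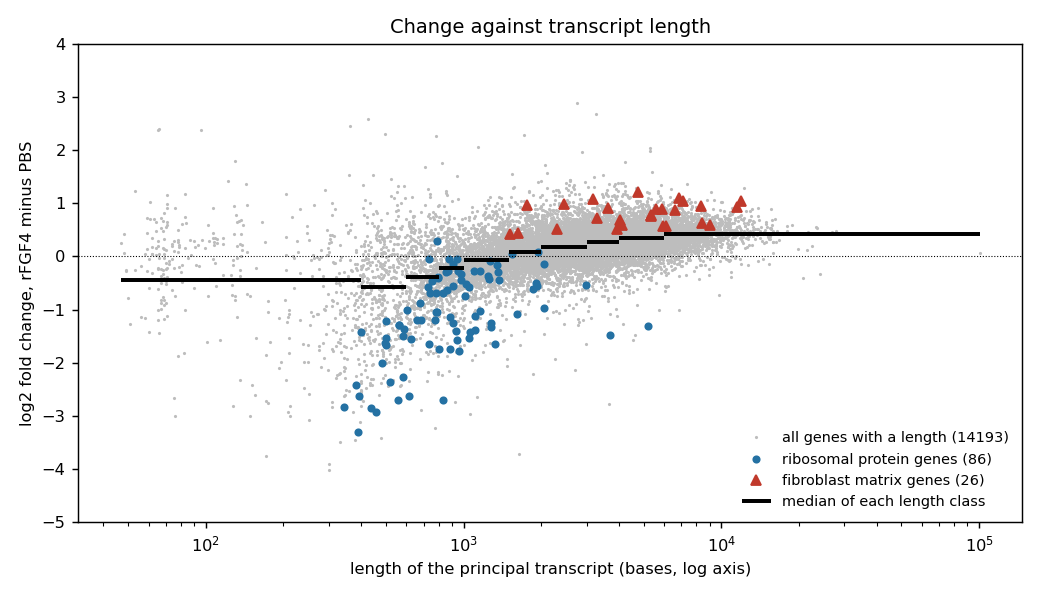
Log2 fold change (rFGF4 minus PBS) against principal transcript length in bases, on a log axis, for 14193 genes (grey points), with 86 ribosomal protein genes (blue), 26 fibroblast matrix genes (red triangles) and the median of each length class (black bars). The medians go from -0.58 at 400 to 600 bases to 0.43 above 6000 bases, and all 26 matrix genes lie above the medians of their length classes.

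Nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain, were lower in 11 of 29 members and in 11 adjusted over the list alone, and 24 of the 29 had negative fold changes (median -0.28, camera adjusted p = 3.76e-12, and adjusted p = 0.807 with an estimated correlation). Ndufa1, Ndufa4, Cox6c and Uqcrb fell by 2.47, 1.48, 1.42 and 1.18 on the log2 scale, with limma adjusted p between 0.00171 and 0.00582. Over all genes 5, 6 and 6 members were called without PBS replicate 1, 2 or 3, and 10, 11 and 8 without rFGF4 replicate 1, 2 or 3. The list has a median transcript length of 1166 bases, and with the length trend removed its median was -0.29 with 9 members lower (camera adjusted p = 2.86e-10, and adjusted p = 0.932 with an estimated correlation). Those 9 have principal transcripts of 419 (Ndufa1) to 1001 bases (Cox7b), all below the list's median length, so the calls that remained still went with short transcripts. Of 15 mitochondrially encoded genes only mt-Nd3, a complex I subunit with a transcript of 348 bases, fell, from 815 ± 88.3 to 190 ± 9.61 FPKM, also adjusted over the list alone (limma adjusted p = 0.00164). The longer mt-Nd5 and mt-Nd4 measured 1.59-fold and 1.48-fold higher and did not pass, and the list's median was 0.16 and its mean 0.02 where camera's direction was down (adjusted p = 0.394, and 0.936 with an estimated correlation). Mitochondrially encoded genes took 14.1%, 16.2% and 14.6% of the listed FPKM in the PBS and 20.6%, 13.9% and 17.8% in the rFGF4 libraries.

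In the epidermis, keratinocytes at a wound edge switch on antimicrobial and cornified-envelope genes, and 3 of 20 such genes were lower with rFGF4, 4 adjusted over the list alone. The protease inhibitor Stfa3 fell from 279 ± 38.0 to 89.0 ± 15.1 FPKM, the beta-defensin Defb14 from 9.03 ± 3.31 to 1.67 ± 0.422 and Sprr2h from 13.7 ± 2.93 to 5.81 ± 1.83 FPKM. The calprotectin subunit S100a8, which like S100a9 is also on the neutrophil list, measured 350 ± 246 and 64.6 ± 34.9 FPKM and did not pass (limma adjusted p = 0.0567). The list's median was -0.22 (camera adjusted p = 0.000415, and adjusted p = 0.714 with an estimated correlation); without PBS replicate 2 it was 0.027 and the call was lost (0.134), as with quantile normalization (0.052). Stfa3 stayed called with each library left out, Defb14 was lost without PBS replicate 1 or 2, and Sprr2h was kept only without rFGF4 replicate 3. These transcripts have a median of 1155 bases, and with the length trend removed 0 members were called by limma, 2 adjusted over the list alone and 4 at an unadjusted p under 0.05, all lower (median -0.32, camera adjusted p = 0.124). Of 21 differentiated keratinocyte genes Krtdap fell over all genes (298 ± 99.03 to 127 ± 2.99 FPKM, limma adjusted p = 0.0409; called only without PBS replicate 3 among the fits that left out a library) and 0 adjusted over the list alone. That list had a median of 0.28 and a mean of 0.13 where camera's direction was down (adjusted p = 0.394), and passed without PBS replicate 3 (0.00652). Krtdap was not called with the length trend removed. Basal keratinocyte and cell-cell junction genes had 0 calls by limma, over all genes and adjusted over the list alone, and 2 each at an unadjusted p under 0.05, with medians of 0.17 and 0.21 and camera's direction down in both (adjusted p = 0.687 and 0.796). The junction list passed without PBS replicate 3 (camera adjusted p = 0.0163).

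Appendage, muscle and fat markers were also read. The 25 hair shaft and inner root sheath genes had 0 calls by limma, also adjusted over the list alone and at an unadjusted p under 0.05, and a median of -0.56 (camera adjusted p = 0.00165, and adjusted p = 0.936 with an estimated correlation), with 23 of 25 fold changes negative. Krtap8-1 measured 19.9 ± 21.9 and 4.39 ± 4.11 FPKM. The hair call was lost without rFGF4 replicate 3 (median 0.18, camera adjusted p = 0.406), with median-centred libraries (0.0889), with quantile normalization (0.0594) and with the length trend removed (0.0734). The 24 skeletal muscle genes had 0 calls by limma, also adjusted over the list alone, with 3 lower at an unadjusted p under 0.05 and a median of -0.41 (camera adjusted p = 0.00011, and adjusted p = 0.936 with an estimated correlation). Troponin Tnnc2 measured 458 ± 165 and 211 ± 70.9 FPKM (limma adjusted p = 0.073). Without rFGF4 replicate 2 the muscle list did not pass (camera adjusted p = 0.155), nor with quantile normalization (0.0913), whereas with the length trend removed it did (median -0.56, adjusted p = 0.00982, and adjusted p = 0.932 with an estimated correlation). In the sebaceous gland list Scd1, a fatty acid desaturase, rose from 106 ± 9.93 to 219 ± 35.2 FPKM as 1 of 14 members, also adjusted over the list alone (camera adjusted p = 0.493, and 0.0329 without rFGF4 replicate 1). Scd1 stayed called only without rFGF4 replicate 1 or 2, and was not called with the length trend removed. Lipoprotein lipase, Lpl, was the 1 call among 14 adipocyte genes (limma adjusted p = 0.0482), with 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. Leaving out any library lost it (0.0627 to 0.142), as did removing the length trend. The adipocyte median was 0.21 where camera's direction was down (adjusted p = 0.942). With an estimated correlation camera's adjusted p for these 2 lists was 0.936 and 0.977.

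Among immune cells, 2 of 14 genes of alternatively activated macrophages rose and 1 fell, or 3 and 1 adjusted over the list alone. Mrc1 was called with each library left out and with the length trend removed (log2 fold change 1.20, limma adjusted p = 0.0029). The haptoglobin-haemoglobin scavenger receptor Cd163 rose from 4.45 ± 0.794 to 8.59 ± 1.87 FPKM, and Retnla, a resistin-like protein with a transcript of 599 bases, fell from 9.12 ± 0.823 to 4.31 ± 1.84 FPKM. Cd163 stayed called only without rFGF4 replicate 1 and Retnla only without rFGF4 replicate 3, and neither was called with the length trend removed. The list had a median of 0.61 (camera adjusted p = 0.394, and 0.936 with an estimated correlation) and passed with the length trend removed (0.43, adjusted p = 0.0475, and adjusted p = 0.932 with an estimated correlation). The 17 general macrophage genes had a median of 0.42 and did not pass camera (adjusted p = 0.491, and 0.936 with an estimated correlation). The 15 neutrophil genes had 0 calls by limma, also adjusted over the list alone, 1 at an unadjusted p under 0.05 and 14 negative fold changes (median -0.23, camera adjusted p = 0.0161, and adjusted p = 0.936 with an estimated correlation). S100a9 measured 1198 ± 904 and 324 ± 222 FPKM. It and S100a8 are also on the wound-edge keratinocyte list, so the 2 lists are not separate evidence on these genes. The neutrophil call was lost without PBS replicate 2 (camera adjusted p = 0.17), PBS replicate 3 (0.153) or rFGF4 replicate 3 (0.06), with median-centred libraries (0.138), with quantile normalization (0.147) and with the length trend removed (0.257). Inflammatory cytokines and mediators had 0 calls by limma in 20 genes, also adjusted over the list alone, and 3 at an unadjusted p under 0.05, with a median of -0.15 and a mean of 0.086 (camera adjusted p = 0.394, direction down, and 0.000441 without PBS replicate 1). Il6 measured 0.884 ± 0.571 and 3.87 ± 2.43 FPKM (limma adjusted p = 0.073), and the chemokine Ccl7 23.7 ± 5.29 and 39.2 ± 4.52 FPKM (adjusted p = 0.0524, and 0.0454 with the length trend removed).

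Of the lists on stress and metabolism, the NRF2 antioxidant response had 1 rise, catalase (Cat, 25.2 ± 3.81 to 38.0 ± 3.01 FPKM), and 1 fall, the superoxide dismutase Sod1 (22.2 ± 2.12 to 12.3 ± 2.15 FPKM, transcript of 641 bases), in 17 genes, and the same numbers adjusted over the list alone. Cat was called in none of the fits that left out a library (limma adjusted p 0.0701 to 0.121) and Sod1 only without rFGF4 replicate 2. Neither Cat nor Sod1 was called over all genes with the length trend removed. Hif1a, the oxygen-regulated transcription factor, rose from 22.4 ± 1.79 to 45.9 ± 8.57 FPKM as the single call among 22 hypoxia and glycolysis genes, also adjusted over the list alone. When a library was left out it stayed called only without rFGF4 replicate 2, and it was not called with the length trend removed. Neither list passed camera (adjusted p = 0.528 and 0.0946), and of the fits that left out a library only the 1 without PBS replicate 1 passed the hypoxia list (0.00838). No gene was called by limma, over all genes or adjusted over the list alone, in the lists for endothelium and angiogenesis (22 genes, median 0.49, camera adjusted p = 0.394), pericytes (10, 0.27, 0.942), myofibroblast contractile genes (12, -0.19, 0.0656), dendritic and Langerhans cells (12, 0.26, 0.796), T and NK cells (12, 0.33, 0.942) and mast cells (7, -0.075, 0.499). The same held for nerve and Schwann cells (10 genes, median 0.028, camera adjusted p = 0.796), melanocytes (9, -0.78, 0.0946), proliferation (27, -0.003, 0.116), the interferon response (20, -0.067, 0.0706), stress and immediate early genes (18, 0.068, 0.449) and blood (9, -0.27, 0.155). Camera's direction was down where the median was positive for T and NK cells, nerve and Schwann cells, stress genes and the NRF2 response, and the mean was positive beside a negative median for mast cells (0.036) and proliferation (0.020). At an unadjusted p under 0.05 these 12 lists held 0 to 3 genes each, with the 3 in endothelium. Leaving out 1 library made some pass camera: endothelium without rFGF4 replicate 2 (adjusted p = 0.00273), dendritic and T cells without PBS replicate 3 (0.0143 and 0.0206), stress genes without PBS replicate 1 (0.019) and blood without rFGF4 replicate 3 (0.0151). Melanocytes passed without PBS replicate 2 (0.0405), rFGF4 replicate 1 (0.0152) or 2 (0.0236), and proliferation without the same 3 libraries (0.00907, 0.0166 and 0.00706). The interferon response passed without PBS replicate 1 (0.0155), PBS replicate 2 (0.00141) or rFGF4 replicate 1 (0.000308), and contractile genes without PBS replicate 1 (0.0225), PBS replicate 3 (0.0432), rFGF4 replicate 1 (0.0475) or 3 (0.0151). With the length trend of the principal transcript removed, none of these 14 lists passed camera, and the smallest adjusted p among them was 0.0528 for hypoxia and glycolysis, which passed with that of the longest transcript removed (0.0371). B and plasma cell genes were too few above the filter to be tested.

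Across the 36 lists tested, 9 passed camera with its preset correlation, 4 higher and 5 lower. With an estimated correlation 0 passed by camera, with 0 at an unadjusted p under 0.05 and the smallest adjusted p at 0.714. The estimates were 0.431 for fibroblast matrix and 0.687 for oxidative phosphorylation, but 0.059 for the TGF-beta pathway and 0.027 for focal adhesion. For FGF-MAPK feedback targets the estimate was -0.044, below the preset 0.01, yet the unadjusted camera p of 0.0158 rose above 0.05. Correlation between genes is therefore not the only reason that calls were lost. Fry, which asks whether a list's genes move 1 way on balance, called 4, and camera on ranks 15. The 4 lists of fry were FGF-MAPK feedback targets, focal adhesion and actin motility, fibroblast matrix and the TGF-beta pathway, each at adjusted p = 0.0104. Fry was run only on the values as deposited and does not compare a list with other genes. Its calls can therefore carry the shift of all genes (median log2 fold change 0.194) and the length trend. Under the 9 other splits of the 6 libraries into 3 and 3, camera called 13 to 20 lists each. Removing the length trend left 7 lists, 5 of them among the 9, and then 7, 12 or 17 without PBS replicate 1, 2 or 3 and 13, 8 or 5 without rFGF4 replicate 1, 2 or 3. As deposited, without PBS replicate 1, 2 or 3 the number was 12, 11 or 15, and without rFGF4 replicate 1, 2 or 3 it was 15, 12 or 8.

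**Figure D3:**
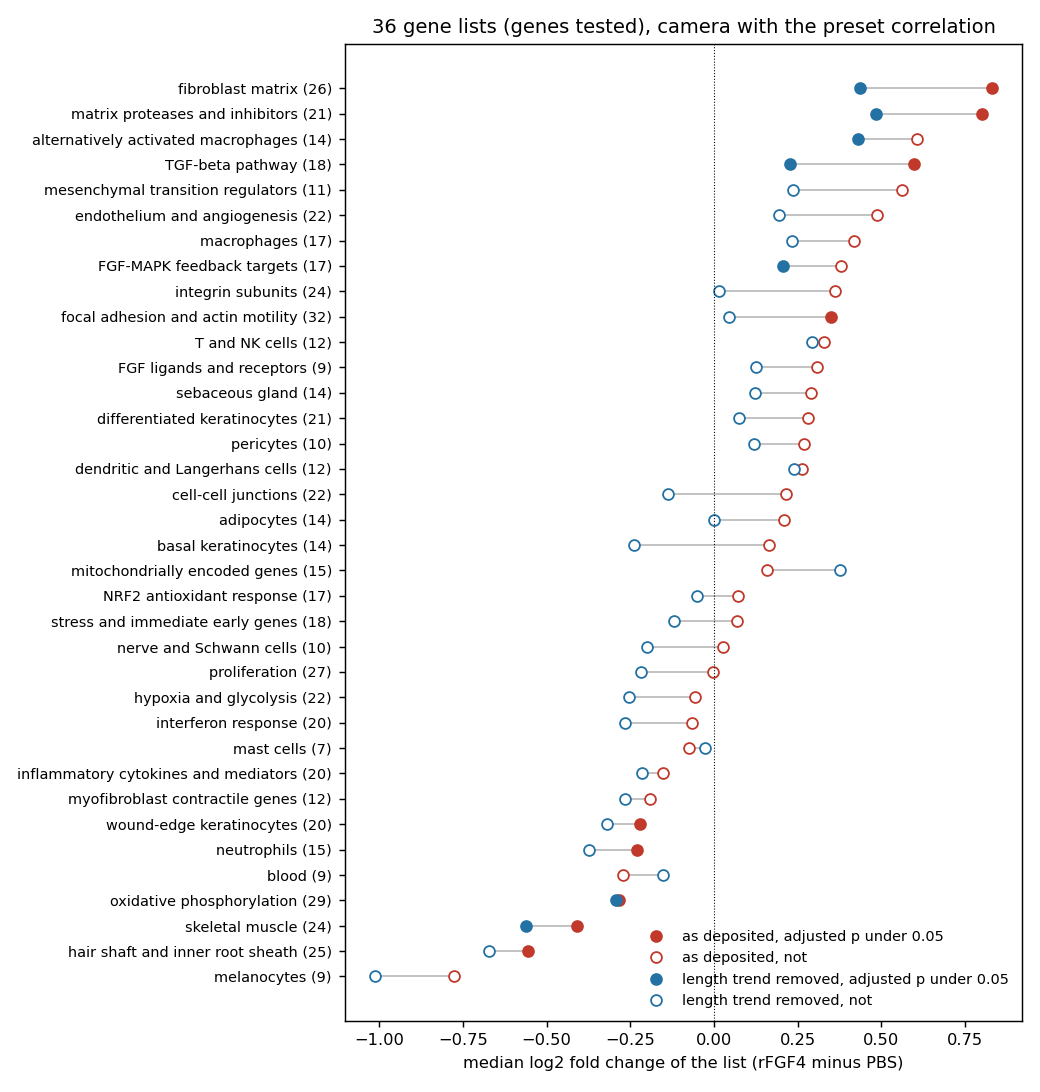
Median log2 fold change (rFGF4 minus PBS) of each of the 36 lists, with the number of genes tested, as deposited (red) and with the length trend removed (blue); filled circles passed camera at its preset correlation. The fibroblast matrix median goes from 0.83 to 0.44 and stays filled, whereas focal adhesion and actin motility goes from 0.35 to 0.044 and does not.

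In the authors' deposited table, 1794 genes had a q-value under 0.05, 725 higher and 1069 lower with rFGF4. The authors' deposited table marks 2301 genes as significant, 1331 higher and 970 lower, with the largest p-value 0.0499 and the smallest fold 1.5. Of the limma calls, 638 of the 1241 higher and 512 of the 532 lower genes also had a q-value under 0.05 in the same direction in the authors' deposited table, and 0 had one in the opposite direction.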

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

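Tests chosen only after the result was seen are those with the length trend removed, with transcripts under 1000 bases left out and with median-centred, total-scaled or quantile-normalized libraries; all others were planned. Against 1773 changed genes (1241 higher, 532 lower), 516 (104 higher) reached 2-fold, a stricter criterion by construction. Removing the length trend left 306 (77 higher, 229 lower), or 316 (63 and 253) by the longest transcript; median centring gave 755 (138 higher) and quantile normalization 749 (235 higher); the muscle covariate gave 366 (91 and 275), and leaving out transcripts under 1000 bases 1280 (1190 higher, 90 lower), with fewer genes tested; the cause of the other moves was not tested. Leaving out 1 library, which lowers the residual degrees of freedom, gave 156 to 890 genes, 24 to 393 higher and 132 to 497 lower. Against 9 changed lists, 15 passed by ranks, 0 with an estimated correlation, 4 by fry, 14 without short transcripts and 8 to 15 with 1 library left out; the cause was not tested. With camera's direction opposite to that as deposited, T and NK cells passed without PBS replicate 3 (camera adjusted p = 0.0206, and up to 0.848 without rFGF4 replicate 3). So did mitochondrially encoded genes with the longest-transcript length trend removed (camera adjusted p = 0.0478). The T and NK cell median was positive both as deposited (0.328) and without PBS replicate 3 (0.866). The cause was not tested. The replicate block gave 233 genes (31 higher, 202 lower) and 10 lists. The labels name no pairing of the samples. In their deviations from the group means, same-numbered libraries correlated at 0.183, -0.067 and -0.125, and the highest value joined PBS replicate 2 and rFGF4 replicate 3 (0.351). With 3 libraries per group, whose deviations sum to 0 for each gene, these values cannot decide whether the numbers pair the samples. Other pseudocounts gave 1819 and 1764 genes, no filter 1628, at least 5 FPKM 1649 and scaling to 1 common total 1938. None of the 60 called genes chosen by the naming rule changed sign in any setting. The alternatives foreseen for counts (other size factors, other count tests, factors without the most abundant genes) were not run, because the table holds no counts. Depth is unknown, so its limits cannot be given.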

Other observations

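Tests chosen only after the result was seen are the length comparison outside the ribosomal and respiratory chain genes, the matrix list against length-matched lists, the shortest-transcript check, the counts, gene calls and set tests with the length trend removed and all values of pathways and of the 14 genes chosen after their values were seen; the other tests were planned before their results.

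Beside the matrix lists, 4 genes chosen after their values were seen rose both as deposited and with the length trend removed, and were called with each library left out. Cilp, a matrix protein of cartilage and fibroblasts, went from 13.4 ± 0.698 to 35.2 ± 3.28 FPKM (limma adjusted p = 0.00263, and 0.00628 with the length trend removed). Abi3bp, a matrix-binding protein gene, went from 8.87 ± 0.1996 to 19.9 ± 0.595 FPKM. Has2, the hyaluronan synthase, went from 2.35 ± 0.356 to 5.99 ± 0.746 FPKM, and Dsel, an epimerase homologue of dermatan sulfate synthesis, from 7.02 ± 0.374 to 15.6 ± 1.17 FPKM. The table's own annotation of chondroitin and dermatan sulfate biosynthesis (18 genes) had a median log2 fold change of 0.49 as deposited and 0.19 with the trend removed (camera adjusted p = 0.0111 and 0.0292; the smallest adjusted p with an estimated correlation over all pathways was 0.999). Among genes of myeloid cells, the endocytic adaptor Dab2 rose from 11.9 ± 0.787 to 29.1 ± 4.21 FPKM, P2ry12 rose 2.31-fold and the chemokine Ccl12 2.13-fold with a transcript of 537 bases. P2ry12 was lost without any PBS replicate or rFGF4 replicate 1, with limma adjusted p up to 0.0788, and Ccl12 was kept only without PBS replicate 3 (0.0439). Other splits of the libraries called 24 to 125 of the 311 pathways, against 49 for the real split, which became 22, 63 and 78 without PBS replicate 1, 2 or 3 and 45, 74 and 23 without rFGF4 replicate 1, 2 or 3.

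Further falls were read in single genes chosen after their values were seen. Sem1, a proteasome lid subunit, went from 22.6 ± 1.26 to 5.44 ± 1.24 FPKM, Polr2l, an RNA polymerase II subunit, from 18.1 ± 2.77 to 5.61 ± 0.950, and Sec61g, of the protein translocon, from 14.7 ± 0.850 to 3.28 ± 1.38 FPKM. The splicing protein Snrpd3 fell by 1.02, the copper chaperone Cox17 by 1.09 and the keratinocyte protease inhibitor Csta1 by 1.30 on the log2 scale (limma adjusted p = 0.0273, 0.00902 and 0.00688). All 6 passed with the length trend removed, but that correction took principal transcripts of 1472 to 3690 bases, whereas the shortest annotated coding transcripts of Sec61g, Snrpd3, Cox17 and Csta1 have 450, 442, 444 and 422 bases. Sec61g was lost without PBS replicate 1 or 3 (limma adjusted p up to 0.0614), Cox17 without PBS replicate 1 (0.0526), and Snrpd3 was kept only without rFGF4 replicate 2 (0.023). The proteasome (44 genes, median -0.16 as deposited) and RNA polymerase (29, -0.030) pathways passed camera with the length trend removed (adjusted p = 0.00268 and 0.00273), the spliceosome (129 genes) with a positive median of 0.059 as deposited and -0.10 after removal. None of the 3 passed with an estimated correlation (adjusted p = 0.999 with an estimated correlation), and with the length trend removed other splits of the libraries called 18 to 97 pathways against 16 for the real split.

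The pattern weighed first is the fall of genes with short transcripts. Each SE given for it comes from resampling genes, which share the same libraries and are not independent replicates. These SEs hold no spread between libraries and understate the uncertainty. The permutation p given below shuffles lengths among ribosomal protein genes, so it too treats genes as independent and holds no spread between libraries. Outside ribosomal and respiratory chain genes, the 886 genes under 700 bases had a median log2 fold change 0.644 lower (-0.644, SE 0.044) than the 9237 over 2000 bases, and within ribosomal protein genes length and fold change correlated at rho 0.534 across genes (permutation p = 1e-05, the smallest that 100000 permutations can give), so a difference in recovery of short transcripts between the groups' libraries may underlie much of the fall; RNA integrity per sample was not used here, and the design joins it with treatment. Within each of 3 classes of GC content the difference kept a size of at least 0.623 (-0.623). That argues against GC content as the whole of the pattern, but not against a part for it. Fold change also correlated with GC content across genes (Spearman's rho -0.39), and the length correction did not remove GC content. The length trend of other genes leaves a remainder. The 70 ribosomal protein and respiratory chain genes of at least 1000 bases lay at -0.324 (SE 0.077) from it. The 42 whose shortest annotated coding transcript has at least 1000 bases lay at -0.348 (SE 0.039). The remainder was larger in shorter genes of these classes, at -0.996 for 114 by principal and -1.202 for 132 by shortest transcript. That trend thus did not take up all of their dependence on length. A fall of these classes beyond length therefore stays open as a hypothesis beside uneven recovery.

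The rise of fibroblast matrix genes was weighed next. Its median of 0.83 lay above all of 10000 random lists matched on length and expression (percentile 100, their highest median 0.49), which argues against the length trend as the whole of it. With the length trend removed, the score of 16 fibroblast identity genes outside the matrix differed by 0.419 (SE 0.12) beside 0.456 (SE 0.12) for the matrix score, and as deposited 6 of the 16 rose, so a higher share of fibroblasts in the sampled rFGF4 tissue is a candidate explanation and a hypothesis. A lower share of keratinocytes and muscle cannot be told apart from it, since the length-corrected difference of the matrix score lay 0.364 above that of the mean of 4 other cell type lists with an SE of 0.23. A rise of matrix transcripts per fibroblast under rFGF4 is a further hypothesis that these bulk libraries leave untested.

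Ucp1 fell 3.72 on the log2 scale (-3.72), with values in rFGF4 libraries from 0.253 to 3.28 FPKM. If less brown-fat-like tissue had been sampled, its other markers should have fallen together. The 13 other brown-fat and thermogenic genes had a median of -0.105 with the length trend removed (SE 0.16, from resampling genes, not libraries). Limma called 0 of them in that setting (3 had an unadjusted p under 0.05), so as a set they did not fall. That cannot decide the question, because the set is not particular to brown fat: Elovl3 and Cidea are also on the sebaceous gland list. Cox8b (-1.79) and Cox7a1 (-1.33) were the lowest of the 13 and Zic1 (0.312) the highest. The fall of Ucp1 stays unexplained.

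The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1773 genes and the highest other split 1, so 1 of the 10 splits gave as many genes. For lists, the real split called 9 and the highest other split 20, so that 10 of the 10 splits gave as many. List medians in other splits reached 2.00 for melanocytes and 1.31 for inflammatory mediators in size. The 5 lists that were lower with rFGF4 all had larger medians in size in another split: oxidative phosphorylation 0.351 against -0.284 in the real split, wound-edge keratinocytes 0.554 against -0.22, hair 1.399 against -0.555, neutrophils 1.26 against -0.229 and muscle 0.849 against -0.408. The 4 higher lists did not, at 0.358 in size against 0.83 for fibroblast matrix, 0.479 against 0.80 for proteases, 0.29 against 0.60 for the TGF-beta pathway and 0.157 against 0.35 for focal adhesion. These medians carry the shift of all genes, 0.194 in the real split. Relative to the median of all genes in each split, a reading added after these values were seen, oxidative phosphorylation was at -0.478 in the real split against 0.336 in size in the others, so that its order turned, while that of the 8 other lists did not. Camera at its preset correlation also called the same lists in some of the 9 other splits. Fibroblast matrix (smallest adjusted p = 6.56e-06) and proteases passed in 5 each, the TGF-beta pathway in 4 and focal adhesion in 2. Oxidative phosphorylation and hair passed in 6 each, wound-edge keratinocytes and muscle in 7 each and neutrophils in 4. A camera call is thus not particular to the real split.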
